A study of Homo sapiens with 4 samples.

How the data were processed

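Total RNA of LNCaP cells was measured on 4 Agilent SurePrint human gene expression arrays, 2 of cells transduced with a control hairpin and 2 of cells with a hairpin against FASN. Per the labels' protocols, cells grew in medium with 10% fetal bovine serum, lentiviral particles were added at a multiplicity of infection of 0.5 to 5, stable transductants were selected with puromycin, and 0.1 µg of RNA was labelled with Cy3. Groups and replicate numbers were taken from the labels.

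Each deposited file of the authors holds spot intensities of 1 array. Per the file headers, they were extracted with Agilent Feature Extraction 10.10.1.1 (10.10 per the submitters' processing notes), which subtracted the background and corrected spatial trends within the array. The processed signal is an intensity on a linear scale, not scaled between arrays. The deposited table of values for the whole series was compared with these intensities spot by spot and its largest difference from them was 0, so the table has no scaling, centring or log of its own. Its column medians were 35.1, 44.3, 29.6 and 31.5 for control arrays 1 and 2 and knockdown arrays 1 and 2. The median background signal was 21 or 22 on every array. Per the file headers, all 4 arrays were on 1 slide and were scanned in 1 scan, with the control arrays at positions 1 and 2 and the knockdown arrays at positions 3 and 4, so position and group cannot be told apart.

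Each array holds 62976 spots, of which 58717 are not controls and belong to 42405 probes. The files give an accession for a probe and no gene symbol. Accessions were matched without version to a RefSeq gene table of assembly GRCh38.p14, which gave 1 symbol to 25715 probes (19720 genes), several symbols to 0 probes, and none to 16690 probes, among them 7660 long intergenic RNA probes and 2714 with an Ensembl transcript. The annotation in the file headers uses another build, so no coordinates are given. A probe without a symbol was kept as a transcript of its own.

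Processed signals were log2-transformed, and the 75th percentile of the non-control spots of the array was subtracted. Spots marked as outliers were left out (364 to 385 per array), as were control spots. Spots of a probe were averaged, and a gene was represented by its probe with the highest mean over the 4 arrays. A gene was tested where that probe was well above background on both arrays of at least 1 group, which left 13885 genes and 7074 unnamed transcripts. A probe counted as well above background where no more of its spots failed than passed, and 999 probes have 10 spots on each array. Where a gene was not well above background in any of its probes in 1 group, the bright group's mean was set against a dim group's mean. Per array, the dim value was the higher of the lowest signal among probes well above background and the probe's own signal. The ratio is given as "at least". It makes no allowance for measurement error, and normexp background correction gave smaller differences for several such genes.

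Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without a block, with Benjamini-Hochberg adjustment over all 20959 genes and transcripts and a threshold of 0.05. The prior degrees of freedom were 1.97, and the smallest difference called among genes was 0.41 on the log2 scale. The groups, the tests, the 21 gene lists and the rule for named genes were fixed before the data were examined. The lists were tested with a one-sided Fisher's exact test per direction against the other tested genes, the test the series' design text states for gene sets, where at least 5 members were tested. The q values are Benjamini-Hochberg adjusted over the 38 tests of 19 lists. Beside it, camera was run with its preset correlation of 0.01 and with a correlation estimated per list. With the preset correlation 7 lists passed after adjustment, and with an estimated correlation camera passed 0 lists, against 2 at unadjusted p under 0.05. Some genes in a list may share regulators and are not independent, so the Fisher values describe overlap.

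The genes named were FASN, then the 12 largest rises and the 12 largest falls among called genes that had a symbol other than a placeholder, were well above background and unsaturated on all 4 arrays, had both arrays of a group beyond both of the other, and had the same sign in every probe well above background on all arrays. They were joined by up to 4 members of each list with the smallest adjusted p in its larger direction, up to 2 called members of the other direction, and the 3 largest bounds in each direction. Some genes chosen by this rule are not reported here. Probes of named genes that were well above background on all arrays had the same sign within a gene. The largest gaps between them were in DDC (2.15 and 1.27) and FABP5 (0.45 and 1.09).

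The spread between the arrays of a group was compared with that between spots. Over the 688 probes with 10 spots that were well above background on all arrays, the SD of the difference between arrays was 5.03 times what the spots predict in the control group and 1.84 times in the knockdown group. Over 19354 genes and transcripts the SD between arrays was 0.199 in the control group and 0.136 in the knockdown group, and Pearson's r across them was 0.996 and 0.998.

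The procedure was tested on simulated data with 20959 genes, in 5 runs with 250 changes of each size in all. The spread of each gene was drawn from the fitted prior, with independent noise and the same spread in both groups. The procedure recovered 0% of changes of 1.5-fold, 2% of 2-fold, 46% of 3-fold and 62.8% of 4-fold and called 0.0116% of unchanged genes. Few genes changed in these runs, with 103800 unchanged over the 5 runs, whereas 14.6% of the real genes were called. The adjustment is stricter where few genes change, so these recovery rates do not carry over to the real data. With 20960 changes of 2.83-fold over the 5 runs, 93.3% were recovered and 0.958% of unchanged genes were called. The real control arrays differed from each other more than the knockdown arrays did, so these rates may not hold for them.

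The alternatives were normexp background correction with an offset of 50, quantile normalization, the median in place of the 75th percentile, the deposited values without scaling, no filter and a stricter filter on dim probes, the mean of a gene's probes, eBayes with trend and robust, the replicate number as a block, each array left out in turn, treat against 1.5-fold, and a requirement of 2-fold. Normexp was planned on the mean spot signal and, as a departure from the plan, was run on the median spot signal. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used to read the files and draw the plots.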

Results

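LNCaP, an androgen-sensitive line grown from a lymph node metastasis of human prostate cancer, was transduced with lentivirus carrying short hairpin RNA and selected with puromycin. Gene expression was measured on 4 Agilent 1-colour arrays, 2 of cells with a hairpin against FASN and 2 of cells with a control hairpin. FASN encodes fatty acid synthase, the enzyme that builds long-chain fatty acids from acetyl-CoA and malonyl-CoA. The comparison asked how the transcriptome of the cells with FASN knockdown differed from that of the control cells. Effects of a hairpin beyond its target, and differences between the selected cell populations, cannot be told apart from the loss of FASN here. Signal at the 75th percentile was 635 and 936 on control arrays 1 and 2, and 528 and 557 on knockdown arrays 1 and 2. Between 61.8% and 64.3% of the non-control spots were well above background and 0 spots were saturated. The number of arrays limits the precision of every value. The labels do not say that the arrays of a group came from separate cultures, and the design text speaks of 2 hybridizations for each sample. The p-values therefore measure only the spread between these arrays, which may be technical.

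FASN was lower in both knockdown arrays. Its level, as log2 signal relative to the array's 75th percentile, was 4.18 ± 0.000327 (SD, n = 2) in the control group and 2.45 ± 0.00764 (SD, n = 2) in the knockdown group, a 3.33-fold lower signal. The difference was -1.73 (SE 0.0777), with a limma adjusted p of 0.00722. The FASN signal was well above background on all 4 arrays, with both spots of its single probe reading 2870 and 2862 on knockdown array 1 against 11550 and 11468 on control array 1. An exact permutation test of 2 values against 2 cannot give a p below 0.333. When dim probes were not filtered out, the adjusted p was 0.0622, and over all alternatives the difference ranged from -2.44 to -1.73.

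Among genes well above background on all 4 arrays, the transcripts that rose most in the knockdown arrays were those of PLA2G2A, a secreted phospholipase, by 3.74 (SE 0.139, adjusted p = 0.00548, 13.3-fold), and SEMG1, a seminal plasma protein, by 3.71 (SE 0.181, adjusted p = 0.00733). They were followed by CA13, a carbonic anhydrase, at 3.52, TRPM8, the cold and menthol channel, at 3.43, and the adrenergic receptor ADRA2A at 3.21. POTEB3 (3.19), CAMK2N1 (3.05), the protease inhibitor SLPI (3.03), the glutamate receptor subunit GRIN3A (2.96), BRINP3 (2.88), the dipeptidyl peptidase DPP4 (2.86) and MAJIN (2.75) also rose, all on the log2 scale. The transcripts that fell most among these genes were those of NAP1L5, at -4.21 (SE 0.154, adjusted p = 0.00548, 18.5-fold lower), and the metallothionein MT1G, at -4.01 (SE 0.0945, adjusted p = 0.00537). GPRIN2 (-3.57), RBPMS2 (-3.46), SPAG16 (-3.43), DPYSL3 (-3.39), the neuropeptide NMU (-2.88), the GABA receptor subunit GABRE (-2.85), the sialyltransferase ST6GAL1 (-2.81), the collagen chaperone SERPINH1 (-2.77), PRXL2A (-2.73) and GMPR (-2.71) fell too. With normexp background correction, which adds an offset, several of these differences were much smaller, though still called, namely 1.74 for SEMG1, -0.97 for DPYSL3, -0.96 for GABRE, -1.57 for RBPMS2, -1.65 for SPAG16, -1.55 for SERPINH1 and -1.40 for GMPR. Over all alternatives the smallest fall was -2.52 for NAP1L5, -2.37 for GPRIN2 and -1.69 for ST6GAL1. MT1G and POTEB3 belong to families of near-identical genes, so their probes may also have read relatives and their values are uncertain.

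In total, 1031 of 13885 tested genes were higher and 998 were lower in the knockdown arrays by limma at the 0.05 threshold after Benjamini-Hochberg adjustment, and 319 and 356 of them differed by at least 2-fold. Among 7074 transcripts without a gene name, 464 were higher and 181 lower. The values of the groups did not overlap for 9844 genes (70.9%). For a single gene, 33.3% is the chance of this if all orders of its values are equally likely. All genes were read on the same arrays, so they are not independent, and array position cannot be told apart from group. The 70.9% therefore cannot be judged against 33.3%, and no conclusion is drawn from it. Without control array 1 the counts were 2287 higher and 1564 lower, without control array 2 they were 589 and 536, without knockdown array 1 they were 129 and 214, and without knockdown array 2 they were 126 and 220. A fit with an array left out takes its spread from the group that kept both arrays, so its counts also follow which group lost an array. With no filter on dim probes limma called 0 genes higher and 1 lower, against 2355 and 1960 at unadjusted p under 0.05.

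The split between higher and lower calls moved with the scaling of the arrays, as the spike-in RNAs also did. Of the called genes, 50.8% were higher with the 75th percentile, 39.8% with the median in its place, and 8.47% without scaling, where 297 genes were higher and 3211 lower. The median difference of all tested transcripts was 0.065, -0.054 and -0.44 in these settings. Relative to the 75th percentile, 7 of 10 spike-in RNAs, the ones well above background, were higher in the knockdown group by 0.71 (SD over the spike-in RNAs 0.048), and lower on control array 2 than on control array 1 by 0.80. Scaled to these spike-in RNAs, an alternative chosen after seeing the data, 148 genes were higher and 2055 lower, 6.72% of the called genes were higher, and the median difference was -0.64. With no scaling and with spike-in scaling the prior degrees of freedom were infinite, against 1.97 in the main setting. Every gene was then given the same spread, so these calls, and list tests on them, are not directly comparable with the main ones. Whether equal amounts of spike-in RNA were added to each sample is not known, so values on the spike-in scale may reflect the amount added. No scaling and spike-in scaling move the difference of every gene by the same amount, with the median of all tested genes at 0.016 in the main setting, -0.49 with no scaling and -0.69 with spike-in scaling. A gene or list that turned sign there kept its place among the other genes. All further differences are relative to the 75th percentile of the array.

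**Figure D1:**
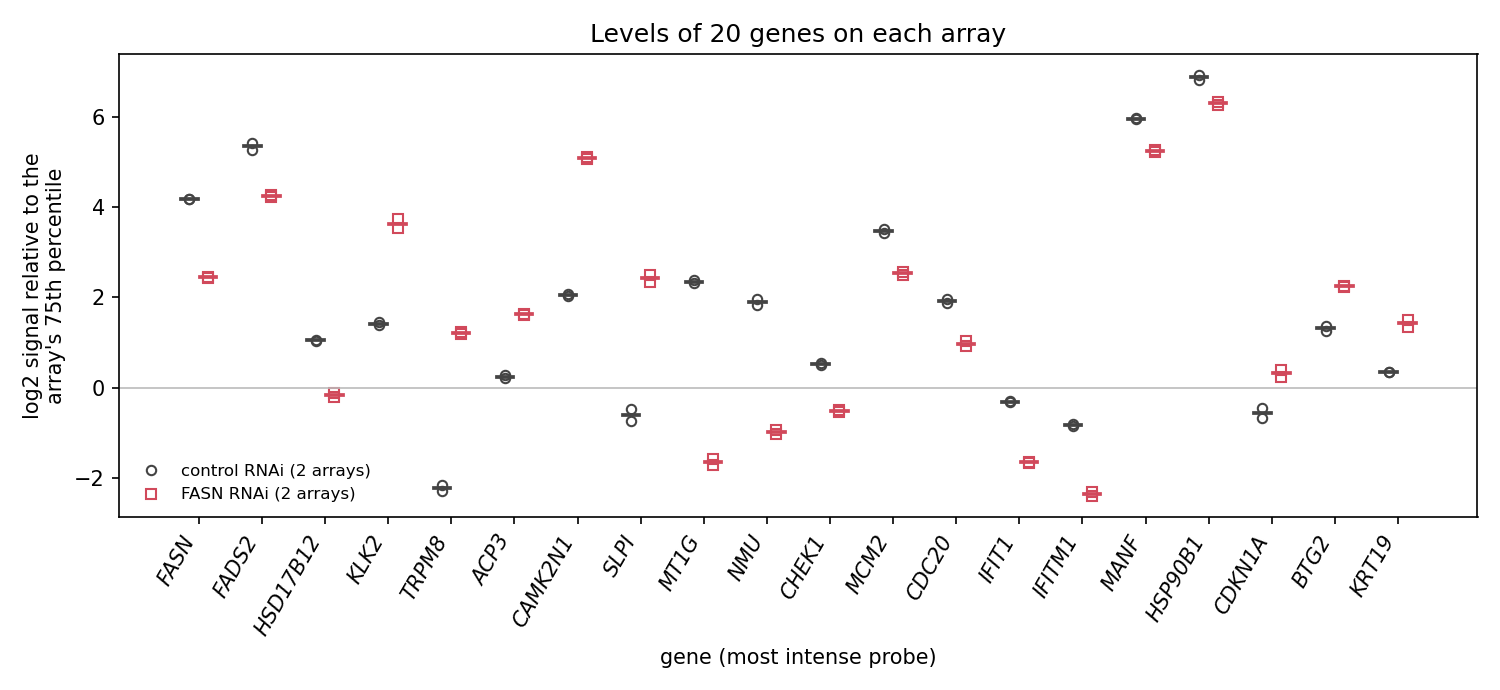
Level of 20 named genes on each array, as log2 signal relative to the 75th percentile of the array (vertical axis), with points for single arrays of the control and knockdown groups and bars for the group means. FASN stood at 4.18 in the control group and 2.45 in the knockdown group, and CAMK2N1 at 2.05 and 5.09.

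Among genes of fatty acid synthesis, 7 of 24 tested members fell and 1 rose, with 7 lower and 2 higher when adjusted over the list alone. Besides FASN itself, transcripts of the elongation enzyme HSD17B12 (-1.21, SE 0.086, adjusted p = 0.0118), the delta-6 desaturase FADS2 (-1.11, SE 0.0985, adjusted p = 0.0157) and the stearoyl-CoA desaturase SCD5 (-1.51) fell, and that of the elongase ELOVL5 rose by 0.83 (SE 0.146, adjusted p = 0.0454). The share of falling genes was above that of the other tested genes by Fisher's exact test, one-sided, q = 0.0108, and q was 0.0259 with FASN left out of the list, an alternative chosen after seeing the data. The list's median difference, 0.021, lay above 0 while its mean, -0.27, lay below, and camera gave an adjusted p of 0.188. The count of falling members was 7 without control array 1 (q = 0.0663), 4 without control array 2 (q = 0.12), 2 without knockdown array 1 (q = 0.496) and 3 without knockdown array 2 (q = 0.11). The list did not pass Fisher's exact test with trend and robust (8 members, q = 0.0691), with no scaling (9 members, q = 0.514) or with spike-in scaling (8 members, q = 0.139).

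Genes of cholesterol synthesis and uptake showed 5 falling members of 26 and no rising member by limma, where 2 members were higher at unadjusted p under 0.05. The lipid transfer protein STARD4 fell by 0.91, HSD17B7 by 0.63, and the late-pathway enzymes EBP and DHCR7 by 0.50 and 0.47. Adjusted over the list alone, 6 fell. Fisher's exact test did not pass (q = 0.125), and camera did (adjusted p = 0.00872), but not with an estimated correlation (adjusted p = 0.332 with an estimated correlation). The count of falling members was 8 without control array 1, and it was 0 by limma without control array 2, knockdown array 1 or knockdown array 2, where 11, 2 and 4 were lower at unadjusted p under 0.05.

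In fatty acid oxidation, 4 of 26 members rose and 2 fell, with 8 and 2 adjusted over the list alone (Fisher's exact test for rising members, q = 0.36). AMACR, the racemase that prepares branched fatty acids for breakdown, rose by 1.26, the beta subunit of the trifunctional protein HADHB by 0.69 and the peroxisomal thiolase ACAA1 by 0.47. The mitochondrial thiolase ACAA2 fell by 0.58, and ACOX2, well above background on 3 arrays, by 1.81, but by 0.22 with normexp background correction (adjusted p = 0.282). Of 26 genes of lipid uptake, activation and storage, 3 rose and 1 fell, also when adjusted over the list alone. These were FABP5 (1.09), DGAT1 (0.55) and SLC27A1 (0.49), and ACSL4, which was not well above background in the knockdown group and was at least 2.59-fold lower there (adjusted p = 0.0213). With normexp background correction ACSL4 turned direction, to 0.20. LPIN1 stood at 0.36 and was not called. Of 8 targets of the sterol receptor LXR, the cholesterol exporter ABCG1 rose by 1.33, SMPDL3A by 0.61 and LPCAT3 by 0.54, while NR1H3, which encodes LXR-alpha, stood at 0.15. The 3 rising LXR targets did not pass Fisher's exact test (q = 0.0727), and 3 rose and 1 fell adjusted over the list alone. Without knockdown array 1 or 2, limma called 0 rising members in each of these 3 lists, against 3, 2 and 3 at unadjusted p under 0.05 without array 1 and 4, 2 and 3 without array 2. Without control array 1 the rising members numbered 7, 4 and 3, and without control array 2 they numbered 3, 0 and 1 (9, 8 and 3 at unadjusted p under 0.05).

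Androgen-responsive genes were shifted upward, with 10 of 34 rising and 2 falling, and 11 and 3 adjusted over the list alone. TRPM8 rose by 3.43, the kallikrein KLK2 by 2.22 (SE 0.11, adjusted p = 0.00733, 4.67-fold), prostatic acid phosphatase ACP3 by 1.38 and EAF2 by 1.29. KLK3, which encodes prostate-specific antigen and was chosen after its values were seen, rose by 0.88 (SE 0.107, adjusted p = 0.0256). ADAM7 and PTGER4 fell, at -1.76 and -1.50. The list held more rising genes than chance by Fisher's exact test (q = 0.00156), its median difference was 0.29, and camera gave an adjusted p of 0.00655 (adjusted p = 0.332 with an estimated correlation). The count of rising members was 12 without control array 1 (q = 0.0391), 9 without control array 2 (q = 0.000161), 3 without knockdown array 1 (q = 0.137) and 4 without knockdown array 2 (q = 0.00923). On the scale of the spike-in RNAs 2 members were called higher (q = 0.321).

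Markers of luminal prostate cells rose in 4 of 10 cases, among them the keratins KRT19 (1.08) and KRT8 (0.45) and the transcription factor GATA2 (0.56), and in 6 adjusted over the list alone. Fisher's exact test gave q = 0.0259 and camera an adjusted p of 0.0127 (adjusted p = 0.332 with an estimated correlation). Without control array 1, 6 members rose, and without control array 2, 2 rose (q = 0.306). Without either knockdown array limma called 0, against 3 at unadjusted p under 0.05 in both cases. Scaling by the median left 2 called members (q = 0.455) and normexp left 1 (q = 0.777), and the list's median difference was 0.44.

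Cell cycle genes were lower as a group. All 45 tested members had a negative difference, 26 fell in the test over all genes and 42 fell adjusted over the list alone. The checkpoint kinase CHEK1 fell by 1.05 (SE 0.0814, adjusted p = 0.0131), the replication licensing factor MCM2 by 0.94 (SE 0.0858, adjusted p = 0.0165), the anaphase activator CDC20 by 0.94 and the transcription factor MYBL2 by 0.80. The list's median difference was -0.61, the one-sided Fisher's exact test gave q = 3.38e-17, and camera gave an adjusted p of 9.91e-16 (adjusted p = 0.332 with an estimated correlation). The shifts were moderate, and 1 member fell by at least 2-fold. Without control array 1 the count was 39 and without control array 2 it was 12 (q = 3.3e-06). Without knockdown array 1 or 2 limma called 0 members, against 22 and 28 at unadjusted p under 0.05, while the list's median stayed at -0.55 and -0.65.

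Among p53 targets, 7 of 25 rose and 1 fell, with 8 and 1 adjusted over the list alone. The antiproliferative gene BTG2 rose by 0.93, the cyclin-dependent kinase inhibitor CDKN1A, which encodes p21, by 0.88, ZMAT3 by 0.79 and SESN1 by 0.78, while the proapoptotic gene PMAIP1 fell by 0.46. Fisher's exact test gave q = 0.0136 and camera an adjusted p of 0.0321 (adjusted p = 0.332 with an estimated correlation). The Fisher test did not pass without control array 1 (7 members, q = 0.359) or control array 2 (3 members, q = 0.365). Without knockdown array 1 or 2 limma called 0 members, against 7 and 6 at unadjusted p under 0.05. With normexp background correction 2 members were called (q = 0.742), and with the median as centre 3 (q = 0.599), and the list's median difference was 0.25.

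Interferon-stimulated genes were lower in the knockdown arrays, with 13 of 29 falling, and 14 falling and 2 rising adjusted over the list alone. IFITM1 fell by 1.54 (SE 0.0863, adjusted p = 0.00875, 2.91-fold lower), IFIT3 by 1.45 (SE 0.0943, adjusted p = 0.0103), IFIT1 by 1.35 and the oligoadenylate synthetase OAS3 by 1.09. The list's median difference was -0.56, Fisher's exact test gave q = 5.51e-07 and camera an adjusted p of 5.85e-05 (adjusted p = 0.332 with an estimated correlation). The count was 13 without control array 1, 5 without control array 2 (q = 0.0587), 3 without knockdown array 1 (q = 0.137) and 3 without knockdown array 2 (q = 0.11). With normexp background correction the list's median was -0.17 and 3 members fell (q = 0.225). IFIT3 then stood at -0.57 and was not called. With no filter on dim probes the median was -0.18 over 38 members, and limma called 0 of them, against 14 falling and 3 rising at unadjusted p under 0.05.

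Chaperones of the unfolded protein response lay low on the knockdown arrays. MANF fell by 0.72, PDIA4 by 0.68, HYOU1 by 0.58 and HSP90B1, the chaperone GRP94, by 0.58. These were the 4 falling members of 18, with 9 adjusted over the list alone, and 17 of the 18 differences were negative. Fisher's exact test did not pass (q = 0.125), while camera gave an adjusted p of 0.00035 (adjusted p = 0.332 with an estimated correlation). The count was 6 without control array 1 and 1 without control array 2, and limma called 0 without knockdown array 1 or 2, against 4 at unadjusted p under 0.05 in both cases. Of 22 genes of the ATF4 and amino acid response, only STC2 was called in the test over all genes and in the test adjusted over the list alone, and it fell by 0.60 (camera adjusted p = 0.881). With normexp background correction STC2 stood at -0.035 and was not called. SLC7A5 stood at -0.67, CTH at -0.31 and PSAT1 at -0.20 in the main setting, none of them called. Without control array 1, 2 members of that list rose and 1 fell, and without each of the other arrays limma called 0 falling members, against 4, 1 and 2 at unadjusted p under 0.05 without control array 2, knockdown array 1 and knockdown array 2.

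Of 25 genes of hypoxia and glycolysis, 4 fell and 2 rose, with 5 and 3 adjusted over the list alone (Fisher's exact test for falling members, q = 0.319). The lactate transporter SLC16A3 fell by 1.40, adrenomedullin ADM by 0.96, phosphofructokinase PFKP by 0.57 and the pyruvate dehydrogenase kinase PDK1 by 0.49, while the prolyl hydroxylase EGLN3 rose by 1.23 and PFKFB4 by 0.42. The falling members numbered 3 without control array 1, 1 without control array 2 and 1 without knockdown array 2, and 0 by limma without knockdown array 1, against 3 at unadjusted p under 0.05.

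Integrins and cell adhesion genes changed in both directions, with 7 of 30 rising and 4 falling, and 9 and 5 adjusted over the list alone. CD44, the hyaluronan receptor, well above background on 3 arrays, rose by 1.07, the laminin chains LAMA3 and LAMA5 by 0.76 and 0.71, and E-cadherin CDH1 by 0.47. Laminin chain LAMB1 fell by 2.09, and P-cadherin CDH3, not well above background in the knockdown group, was at least 2.91-fold lower there (adjusted p = 0.00917). With normexp background correction CDH3 stood at -0.0077, and neither CDH3 nor CD44 was called. Fisher's exact test for rising members gave q = 0.0259, the list's median was 0.12, its mean was -0.024 and camera gave an adjusted p of 0.44. The rising members numbered 9 without control array 1 (q = 0.179) and 4 without control array 2 (q = 0.199), and limma called 0 without knockdown array 1 or 2, against 6 and 7 at unadjusted p under 0.05. Normexp left 2 rising members (q = 0.773) and the median as centre left 5 (q = 0.219).

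Of 16 invasion and mesenchymal genes, 5 rose, with 7 rising and 2 falling adjusted over the list alone. Fibronectin FN1 rose by 1.79 (SE 0.222, adjusted p = 0.0269), the matrix metalloproteinases MMP7 and MMP15 by 1.22 and 0.73, and the transcription factor SNAI1 by 0.73. Fisher's exact test gave q = 0.0259 and camera an adjusted p of 0.08. The count was 8 without control array 1 (q = 0.0217) and 3 without control array 2 (q = 0.178), and limma called 0 without knockdown array 1 or 2, against 6 and 5 at unadjusted p under 0.05. Normexp left 3 rising members (q = 0.0977), the median as centre left 4 (q = 0.105), and with trend and robust 6 rose (q = 0.105). Among 39 regulators of actin and pseudopodia, the GTPase RHOB rose 2.14-fold, the membrane linker EZR by 0.77 on the log2 scale and the Arp2/3 subunit ACTR2 by 0.59, while the formin DIAPH3 fell by 0.87 and CDC42EP1 by 0.70. These were 3 rising and 2 falling members, with 6 and 2 adjusted over the list alone, and Fisher's exact test did not pass (q = 1, camera adjusted p = 0.0682). MSN stood at 0.40 and was not called. The rising members of this list numbered 6 without control array 1 and 2 without control array 2, and limma called 0 without knockdown array 1 or 2, against 4 at unadjusted p under 0.05 in both cases.

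Markers of other cell types gave few calls. Of 16 neuroendocrine markers 4 could be tested, and SYT4 (0.96) and DDC (1.27) rose, also adjusted over the list alone, too few members for a list test. Limma called 0 of 5 basal markers and 0 of 4 fibroblast markers, also adjusted over the list alone, although KRT14 stood at 1.03, KRT15 at 0.42, DST at 0.36, S100A2 at 0.35, COL5A1 at 0.25 and S100A4 at 0.21. Of 9 leukocyte markers, CD68, a lysosomal protein found in many cells, rose by 0.87, and 2 rose adjusted over the list alone, while SPI1 stood at 0.66, CD79A at 0.48 and CD8A at 0.24. Of 15 housekeeping genes 1 was called lower, also when adjusted over the list alone, and TFRC (-0.18), GAPDH (-0.17) and PGK1 (-0.070) were not called. Without control array 1, 3 basal, 1 fibroblast and 3 leukocyte markers were called higher. Without knockdown array 1 or 2 limma called 0 neuroendocrine and 0 leukocyte markers, against 2 and 1 at unadjusted p under 0.05 without array 1 and 2 and 2 without array 2.

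Several genes were well above background in 1 group alone, and their ratio is given as a bound. Where the dim value was the probe's own signal, as for PCP4L1 (-6.18), the bound is the measured difference and not a minimum. HSPA1A was at least 21.9-fold higher in the knockdown group, ADGRF1 at least 11.7-fold and the seminal plasma protein SEMG2 at least 10.0-fold. The probe of HSPA1B, a near-identical gene chosen after its values were seen, differed by 0.20 (SE 0.0787, adjusted p = 0.169), so the HSPA1A value is uncertain. The peroxidasin gene PXDN was at least 225-fold lower in the knockdown group, PCP4L1 at least 72.7-fold and MLKL, the effector of necroptosis, at least 26.1-fold. The adjusted p of these 6 genes ranged from 0.00149 for PXDN to 0.0258 for SEMG2. With normexp background correction all 6 log2 differences were smaller than the bounds. They were 1.71 for HSPA1A, 1.19 for ADGRF1 and 1.04 for SEMG2, with ADGRF1 and SEMG2 not called. PXDN stood at -4.09, PCP4L1 at -2.89 and MLKL at -1.50. In total 99 genes were well above background in the knockdown group alone, 97 of them by a bound of at least 2-fold. In the control group alone there were 282, of which 272 had a log2 bound above 0 and 145 a bound of at least 2-fold. Limma called 47 of the 99 and 131 of the 282. More spots were well above background on the control arrays (63.1% and 64.3%) than on the knockdown arrays (62.0% and 61.8%), so the 2 totals are not directly comparable.

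**Figure D2:**
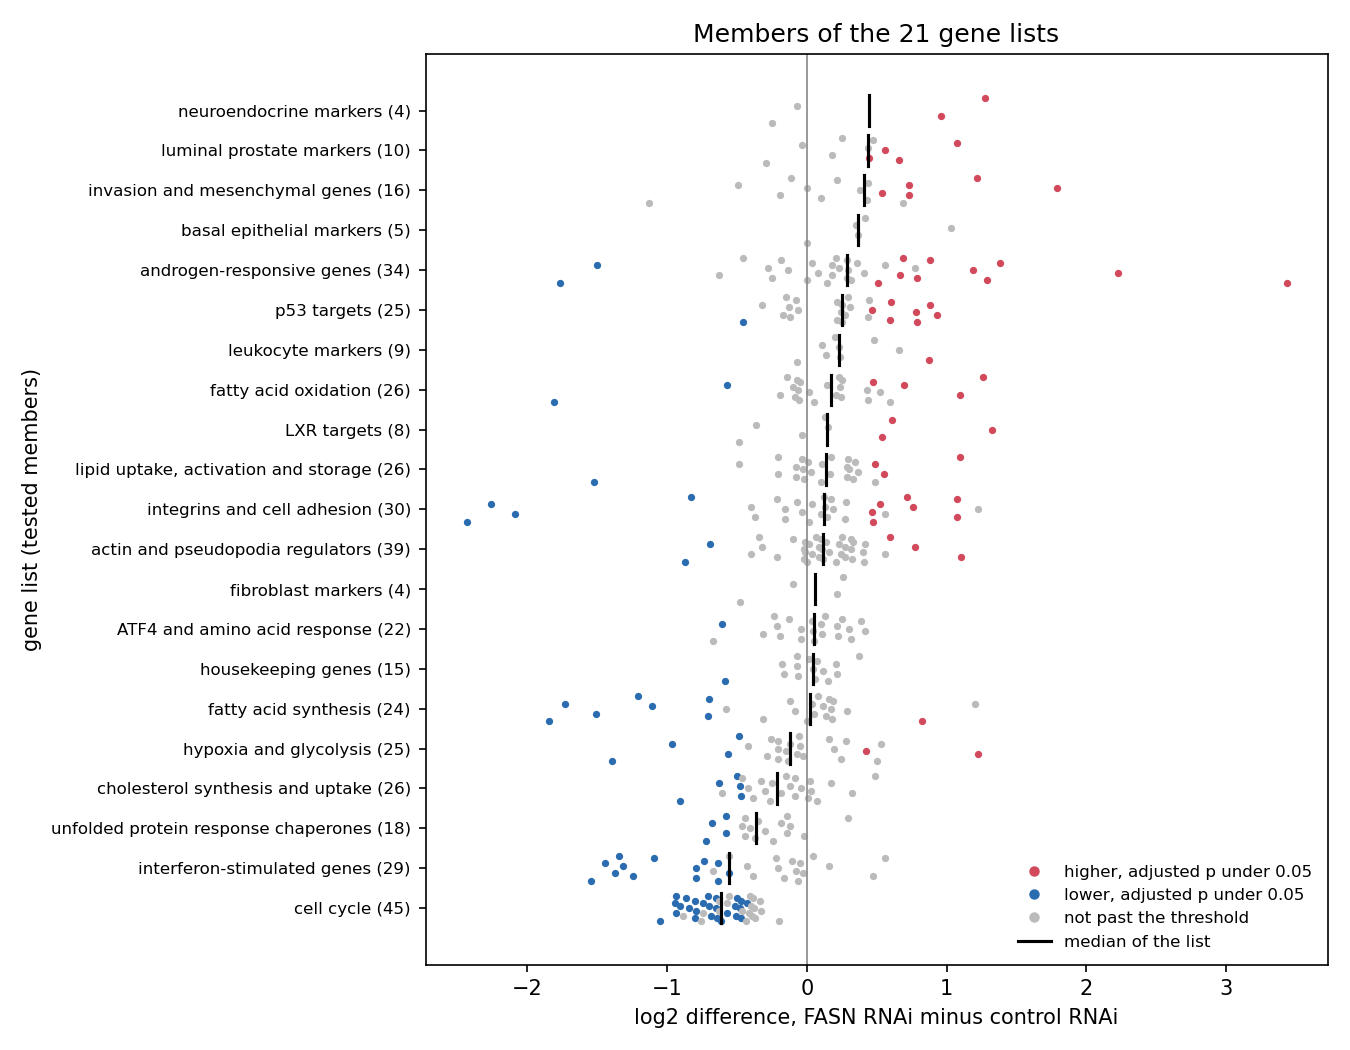
Difference between the groups (log2, knockdown minus control, horizontal axis) of every tested member of 21 gene lists, with points for genes, red where called higher, blue where called lower and grey where not called, and black bars for list medians. The 45 cell cycle genes all lie below 0 with a median of -0.61, and the androgen-responsive genes have a median of 0.29.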

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

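The spike-in scaling, and the list without FASN, were alternatives chosen after seeing the data, and the others were planned. FASN stayed lower under every alternative scored, from -2.44 to -1.73, and lost its call only with no filter on dim probes (-1.73, adjusted p = 0.0622). FASN and the lists were not scored with treat against 1.5-fold. Over 118 named genes and 1642 values, 1200 kept direction and side of the threshold, 384 kept direction without the call, 17 gained a call and 41 turned direction. Of the turns, 15 came with no scaling and 22 with spike-in scaling, which move every gene by the same amount, so these follow from that shift. The cause was not tested for any change below, except that fewer arrays leave fewer degrees of freedom, no filter adds dim genes to the test, and a stricter threshold or fold admits fewer genes.

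Counts of genes higher and lower, 1031 and 998 in the main setting, were 438 and 377 with normexp, 297 and 3211 with no scaling, 0 and 1 with no filter (limma, 2355 and 1960 at unadjusted p under 0.05), 2250 and 2087 with trend and robust, 118 and 166 with treat against 1.5-fold, 319 and 356 at 2-fold as well, 429 and 415 for a 2-fold mean difference with no test, and 148 and 2055 with spike-in scaling. Leaving out an array gave 126 to 2287 higher and 214 to 1564 lower genes. The lone array was assumed to vary like the other group's. The spread was then that of the knockdown arrays (SD 0.136) where a control array was left out. It was that of the control arrays (SD 0.199) where a knockdown array was left out. Fewer calls without a knockdown array therefore do not by themselves show that the result depended on that array. With quantile normalization, the median as centre, the stricter filter and the mean of probes, the counts stayed within 1.5 times.

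Lists past the Fisher threshold numbered 8 in the main setting and, not always from among those 8, 3 with normexp, 5 with the median as centre, 5 with no scaling, 3 with spike-in scaling, 3 when only calls of 2-fold counted, and 0 with no filter, where no list had an unadjusted p under 0.05. Camera with an estimated correlation passed 0 (2 at unadjusted p under 0.05), and 0 to 6 lists passed when an array was left out. By Fisher's exact test the cell cycle list lost its call with no filter, when only calls of 2-fold counted and without either knockdown array alone, and the androgen list with no filter, with spike-in scaling and without knockdown array 1. Over single probes well above background on all arrays, the SD between control arrays over that between knockdown arrays was 1.45, and 2.28 with normexp.

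With the replicate number as a block, 389 genes were higher and 422 lower, of which 377 and 406 were also called without it, and 4 lists passed. Whether same-numbered arrays shared more than a number is not known. The differences between replicates 1 and 2 correlated between the groups at 0.114 across genes and transcripts, which cannot settle it. A block for slide or scan was not run, because there was 1 of each.

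Direction turned with normexp for ACSL4 (0.20) and SLC7A5 (0.0087), with the mean of probes for DST (-0.014), and without control array 2 for S100A4 (-0.043, against 0.47 without control array 1). Normexp brought STC2 to -0.035, CDH3 to -0.0077, CD44 to 0.50, IFIT3 to -0.57, ADM to -0.40, ADGRF1 to 1.19 and SEMG2 to 1.04, all without the call, and left HSPA1A at 1.71, PXDN at -4.09, PCP4L1 at -2.89 and MLKL at -1.50, with the call. With no scaling direction turned for ACAA1 (-0.034), SLC27A1 (-0.017), LPIN1 (-0.14), NR1H3 (-0.35), CDH1 (-0.035), MSN (-0.11), PFKFB4 (-0.086), KRT8 (-0.062), DST (-0.14), S100A2 (-0.15), KRT15 (-0.091), COL5A1 (-0.25), S100A4 (-0.30), CD8A (-0.27) and CD79A (-0.030). With spike-in scaling it turned for HADHB (-0.014), ACAA1 (-0.23), SLC27A1 (-0.22), DGAT1 (-0.16), LPIN1 (-0.34), SMPDL3A (-0.097), LPCAT3 (-0.17), NR1H3 (-0.55), CDH1 (-0.23), ACTR2 (-0.12), MSN (-0.31), PFKFB4 (-0.29), GATA2 (-0.15), KRT8 (-0.26), DST (-0.34), S100A2 (-0.35), KRT15 (-0.29), COL5A1 (-0.45), S100A4 (-0.49), SPI1 (-0.045), CD8A (-0.47) and CD79A (-0.23). Signal over background limits the dim genes, since spots well above background made up 61.8% to 64.3% of each array.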

Other observations

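The gene families below, the count of slide positions shared by the groups and the count of arrays without a vector were tests chosen after the result was seen. The q values of the families therefore describe overlap and are no independent support. Beta-protocadherins, clustered adhesion genes best known from neurons, rose in 9 of 12 tested cases, with a median difference of 1.34 (Fisher's exact test over 12 families and both directions, q = 2.86e-07). PCDHB16 rose by 1.85 (SE 0.136, adjusted p = 0.0124), PCDHB15 by 1.71 and PCDHB8 by 1.69. PCDHB12, not well above background in the control group, was at least 4.06-fold higher in the knockdown group. The family's median was 0.77 with normexp, 1.26 with quantile normalization, 1.22 with the median as centre, 0.84 with no scaling and 0.64 on the scale of the spike-in RNAs. The count of called members was 7 with normexp, 6 with no scaling, 3 with spike-in scaling, 6 with the replicate block, 0 with no filter (12 at unadjusted p under 0.05), 9 and 7 without control arrays 1 and 2, and 4 and 5 without knockdown arrays 1 and 2. The genes are close in sequence, so probes can read more than their own gene.

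Enzymes that attach glucuronic acid to steroids and drugs changed in both directions, and subfamilies were not tested. UGT2B4, not well above background in the knockdown group, was at least 6.70-fold lower there, and UGT2B7 (-1.94), UGT2B11 (-1.08) and UGT2B10 (-0.85) fell. UGT2B15 (-0.47, adjusted p = 0.0509) was not called, while UGT1A6 (2.11) and UGT1A8 (2.14, well above background on 3 arrays) rose. The family held 4 falling members of 7 (Fisher's exact test, q = 0.00934), its median was -0.85 and, with normexp, -0.51, and 2 members fell without knockdown array 1 or 2. Products of UGT1A genes share exons, so the UGT1A values are uncertain. Replication-dependent histones fell in 11 of 61 cases (q = 0.0301), among them H2BC12 (-0.84) and H3C11 (-2.15), and the family's median was -0.24, with -0.23 under normexp and -0.27 under quantile normalization. That median was -0.035 without control array 1, and 1 member fell without knockdown array 1 or 2. Metallothioneins had 3 falling members of 10 (q = 0.146), led by MT1G (-4.01) and MT1E (-0.996). The family's median was -0.43, with -0.48 under normexp and -0.47 under quantile normalization, and the count was 5 without control array 1, 2 without control array 2 and 1 without either knockdown array.

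The 45 cell cycle genes had a median difference of -0.61. Against an intensity-dependent difference in scale between arrays, that median lay at percentile 0 among 10000 random lists matched on mean signal, whose 1st percentile was -0.12. Against an effect of the bright control array 2, the median without it was -0.52. Array position and group handling cannot be told apart from the knockdown, since 0 slide positions were shared by the groups. A slower cycle after FASN knockdown is a candidate explanation. Differences between the cell populations selected under puromycin are another, and neither was tested.

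Interferon-stimulated genes had a median difference of -0.56. That median lay at percentile 0 among 10000 matched random lists, which argues against an intensity-dependent difference in scale, although it was -0.17 with normexp and -0.18 over 38 members with no filter on dim probes. Without control array 2 it was -0.55, which argues against an effect of that array. A candidate explanation is that the control hairpin raised the interferon response more than the FASN hairpin did. Both groups carried lentivirus, and an effect of it that was equal in both would cancel. This explanation cannot be told apart from a fall caused by FASN knockdown, since 0 arrays of cells without a vector were measured.

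Androgen-responsive genes had a median difference of 0.29, at percentile 100 among 10000 matched random lists, which argues against an intensity-dependent difference in scale. A candidate explanation is higher activity of the androgen receptor, and genes that androgen represses would then fall. The median of 6 such genes, listed before their values were seen, was -0.51, but called members went both ways. CCN3 (-1.39) and MET (-1.29) fell, BCHE (1.22) and ACKR3 (0.65) rose, and UGT2B15 (-0.47) and OPRK1 (-0.54) were not called. The hypothesis remains open.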
